A study of Mus musculus with 8 samples.

How the data were processed

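RNA from mouse sperm was extracted with a Qiagen miRNeasy kit, and libraries were sequenced as 50 nt single-end reads on an Illumina NextSeq500, per the labels' protocols. The count table holds whole-number read counts per mature miRNA for 8 samples, as deposited by the authors. The trimming, aligner, miRNA reference, genome build and any count filter are not given in the sources used here. The authors' deposited table also holds group means of the counts (used here as a score with no error), log2 fold changes with average log2 CPM, and p-values with FDR; edgeR is named in the submitters' processing notes, with no version.

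Groups and replicate numbers were taken from the sample titles. Libraries of one group differed by more than counting noise (chi-square per degree of freedom from 3.31 to 61.5), so all 8 were used as separate samples. The groups, tests, 26 miRNA lists, the rule for named miRNAs and the first set of other settings were fixed before the data were examined. After the names in the table were seen, 4 older names were matched to list members (miR-142, miR-486, miR-3107 and miR-292).

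The main test was edgeR 4.0.16 (R 4.3.3) with TMM factors, its default expression filter by group, robust quasi-likelihood F tests (two-sided) and Benjamini-Hochberg adjustment. The filter kept 226 miRNAs and left out 161, which held 0.258% of counts. Normalised CPM values are counts scaled by the library total and its TMM factor. Standard errors are the size of the log2 fold change divided by the t quantile of its p-value. Lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over 20 lists. fry tests whether a list moves one way, without comparing it with other miRNAs. List lengths count each named arm. Library measures used exact permutation tests over 70 assignments (scipy 1.17.1). Hairpin positions come from the GENCODE annotation of GRCm38 and are those of the hairpin gene of the same name; the tables name no build.

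The rule for named miRNAs took those past FDR 0.05, the 10 most abundant, the 5 higher and 5 lower with the smallest unadjusted p where fewer than 10 passed, the 2 most abundant of each list, the measured members of the paternal stress list, and the 5 smallest p in the authors' table if none passed there. The paternal stress list was recalled as background and is not a complete survey.

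The method was tested on 20 simulated data sets, with 40 of 226 miRNAs changed in each. The simulated counts used the means, library sizes and dispersions of these samples, and each miRNA varied independently of the others. The method called 88.8% of miRNAs changed 4-fold, 71.5% of those changed 2-fold, 27.1% of those changed 1.5-fold and 0.40% of unchanged ones. Simulations of 226 miRNAs with no change gave a mean of 9.65 miRNAs at an unadjusted p under 0.05. At 193013 to 261903 counts per library, a miRNA at 10 CPM has 2 to 3 reads. Intervals and errors cover the spread between samples. Reads carry no molecular identifiers in the sources used here, so counts are reads and not molecules.

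Other settings chosen at that point were other scaling factors (RLE, library total, upper quartile), no count filter, a filter of 10 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, the test without robust estimation, the replicate number as a block, leaving out each replicate, and totals without the 10 most abundant miRNAs. Settings chosen after seeing the data were other edgeR tests, covariates, totals without red blood cell miRNAs, thinned libraries and leaving out Exposed 2 with Trained 3. Pseudocounts were not varied, since the values are counts.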

Results

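Small RNA sequencing of mouse sperm gave counts of mature miRNAs, the short RNAs that direct repression of messenger RNAs, in 8 samples from C57BL/6 animals 2 months old. The samples fell into 2 groups of 4, named Exposed and Trained. The study examined sperm miRNA after treatments related to smell, and the labels describe the treatments no further. No untreated group was analysed here. The count table listed 387 mature miRNAs. Its totals were 241885, 208900, 254944 and 193013 counts in Exposed 1 to 4, and 250458, 260685, 261903 and 239664 counts in Trained 1 to 4. These totals are the reads assigned to the listed miRNAs and lie far below the reads per sample that the labels state, so they are not the sequencing depth. Nothing in the labels says that the 4 samples of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

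The sperm miRNA content was led by miR-34c-5p, a member of the miR-34 and miR-449 family of spermatogenic and ciliated cells, at 111406 ± 3522 normalised CPM (SD, n = 4) in Exposed and 110551 ± 9861 CPM (SD, n = 4) in Trained. It was followed by miR-881-3p at 87085 ± 14274 CPM in Exposed and 82405 ± 21126 CPM in Trained, and by miR-465b-5p at 66122 ± 7487 and 65666 ± 6610 CPM. let-7a-5p stood at 63795 ± 5018 CPM in Exposed and 57365 ± 3530 CPM in Trained. The other 6 of the 10 most abundant miRNAs were miR-21a-5p, miR-465c-5p, miR-191-5p, miR-184-3p, miR-128-3p and miR-148a-3p, with means over all samples from 40824 down to 23833 CPM. The log2 fold changes of these 10, Trained over Exposed, lay between -0.15 for let-7a-5p and 0.08 for miR-191-5p, and none passed the test (FDR = 0.998, edgeR quasi-likelihood). With library totals alone the sign turned for miR-34c-5p, miR-465b-5p, miR-21a-5p, miR-465c-5p, miR-128-3p and miR-148a-3p. miR-465b-5p and miR-465c-5p are near-identical, so the split of reads between them is uncertain. The X-linked testis cluster, a set of rapidly evolving miRNAs expressed in male germ cells, held 29.7% ± 1.84 (SD, n = 4) of counts in Exposed and 29.3% ± 3.31 (SD, n = 4) in Trained.

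**Figure D1:**
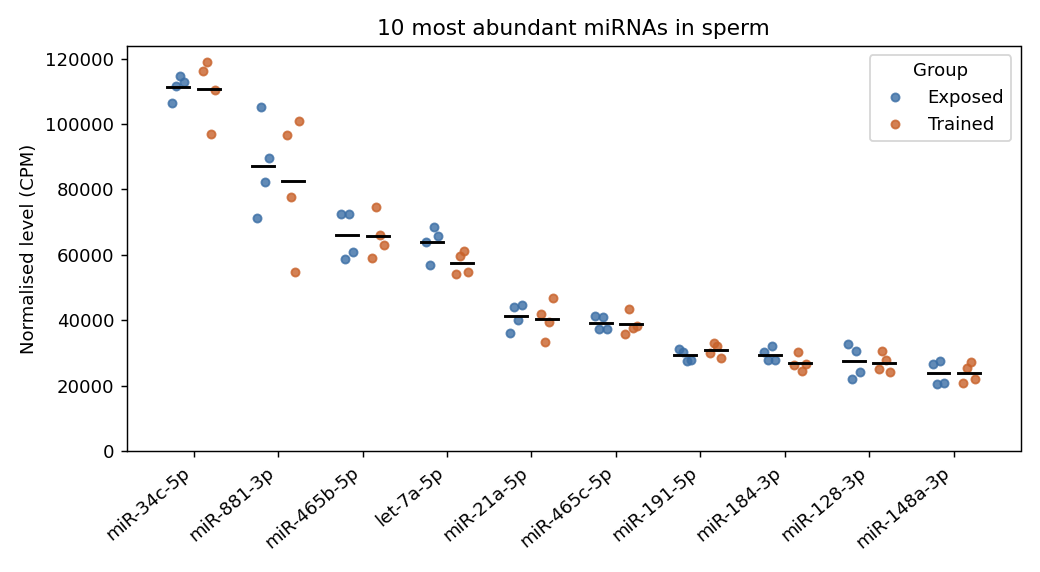
Normalised level (CPM) of the 10 most abundant miRNAs in each library, with Exposed and Trained libraries as points and the group mean as a black line. miR-34c-5p had the highest mean in both groups, and miR-881-3p ranged most widely between libraries in absolute terms.

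Trained was compared with Exposed to ask whether sperm miRNA levels differed between the treatments. Of 226 miRNAs tested, 0 passed an FDR of 0.05 by edgeR's quasi-likelihood test, and the smallest FDR was 0.998. An unadjusted p under 0.05 was found for 10 miRNAs, 9 lower and 1 higher in Trained, where 11.3 are expected by chance. The split by direction was 7 higher and 3 lower without Trained 2, 7 higher and 2 lower without Exposed 2 and Trained 3, and 2 higher and 1 lower with the smooth muscle and stroma score as a covariate. DESeq2 and limma-voom also gave 0, with 10 and 8 at an unadjusted p under 0.05. The 95% interval of a fold change had a median half-width of 0.45 on the log2 scale. In simulated data built on these libraries, the test called 71.5% of miRNAs changed 2-fold and 27.1% of those changed 1.5-fold among 226 miRNAs. Each simulation changed 40 miRNAs at once, and each miRNA varied independently of the others. The share called where few miRNAs change, or where miRNAs move together, was not measured.

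The miRNAs with the smallest unadjusted p on each side did not pass the test and are given as values. Lower in Trained was miR-206-3p, a skeletal muscle miRNA, at 180 ± 83.6 CPM against 411 ± 197 CPM in Exposed (SD, n = 4; log2 fold change -1.19, SE 0.39, FDR = 0.998 by edgeR). The muscle miRNA miR-1a-3p stood at 638 ± 230 CPM in Trained and 1148 ± 462 CPM in Exposed (log2 fold change -0.85, and -0.53 without Exposed 2). miR-10a-5p (log2 fold change -0.34, SE 0.12), miR-7214-5p (-0.53, SE 0.19) and miR-152-3p (-0.34, SE 0.13) were the other 3 on that side. Higher in Trained were miR-342-3p (0.57, SE 0.24), miR-150-5p (1.35, SE 0.65), miR-96-5p (0.56, SE 0.28), miR-186-5p (0.32, SE 0.19) and miR-185-5p (0.30, SE 0.18). miR-150-5p, a lymphocyte miRNA, reached 1847 CPM in Trained 3, and between 177 and 846 CPM in the other Trained libraries. Without Trained 3 the log2 fold change was 0.61 for miR-150-5p, 0.36 for miR-342-3p and 0.13 for miR-186-5p, and without Exposed 1 it was 0.19 for miR-185-5p. With limma-voom it was 0.89 for miR-150-5p.

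In the GRCm38 annotation, the hairpin gene Mir206 lies on chromosome 1 at 20679010 to 20679082, in an exon of the long non-coding RNA gene Gm28653. Mir10a is on chromosome 11 at 96317165 to 96317274 with no overlapping gene, and Mir152 on chromosome 11 at 96850393 to 96850465 in an intron of Copz2. Mir342 lies on chromosome 12 at 108658620 to 108658718 in an intron of Evl, and Mir150 on chromosome 7 at 45121757 to 45121821 with no overlapping gene. miR-1a-3p is encoded by a pair of hairpins, on chromosome 2 at 180389048 to 180389124 and on chromosome 18 at 10785481 to 10785552.

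**Figure D2:**
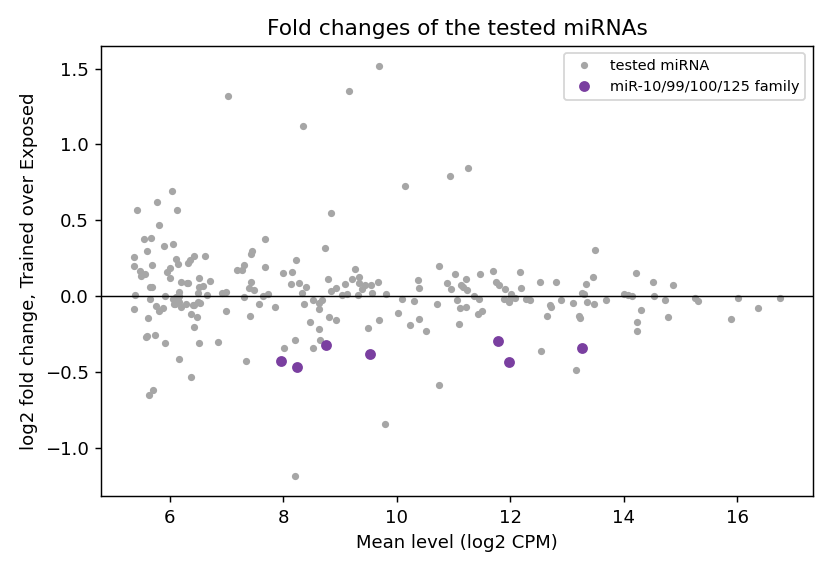
log2 fold change, Trained over Exposed, against mean level (log2 CPM) for the 226 tested miRNAs. The 7 tested members of the family of miR-10, miR-99, miR-100 and miR-125, in purple, all lie below 0, with a median of -0.38.

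Among 20 miRNA lists with 3 or more tested members, 1 passed camera with a preset correlation, the family of miR-10, miR-99, miR-100 and miR-125, whose miR-10 genes lie within the Hox clusters. All 7 tested members had lower fitted values in Trained, with a median log2 fold change of -0.38 (camera adjusted p = 5.91e-05). The call was lost with the members' own correlation, with an adjusted p = 0.367 with an estimated correlation and 0.350 by fry. None of the 7 passed FDR 0.05 over all miRNAs or adjusted over the list alone. The 2 most abundant were miR-10a-5p, at 8707 ± 552 CPM in Trained and 11030 ± 1493 CPM in Exposed, and miR-10b-5p, at 3456 ± 208 and 4670 ± 1430 CPM (log2 fold change -0.43, and -0.21 without Exposed 2). Without Exposed 2, the library with the highest summed level of this family (26890 CPM), the median was -0.16 (camera adjusted p = 0.0315). That call was lost with an estimated correlation (adjusted p = 0.394) and by fry (0.105). The same library also held the highest summed levels of the striated muscle list (3121 CPM) and of the smooth muscle and stroma list (15886 CPM). The mean log2 level of the striated muscle list was higher in all 4 Exposed libraries (9.10 to 9.79) than in all 4 Trained libraries (8.34 to 9.09; exact permutation p = 0.0286, unadjusted, the smallest that 4 against 4 allows), a test chosen after the values were seen. For its summed CPM the exact permutation p was 0.0571 (adjusted 0.357 over 25 lists). The call was lost without Exposed 2 and Trained 3 (median -0.12, adjusted p = 0.105), and with a covariate for smooth muscle and stroma (-0.15, adjusted p = 0.0631) or for striated muscle (0.05, adjusted p = 0.887).

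Lists of miRNAs from other cell types did not pass the preset test in the main fit, but some passed under other settings. With the replicate number as a block the red blood cell, striated muscle, and smooth muscle and stroma lists passed, calls lost with an estimated correlation (adjusted p = 0.536). Of the 3 tested striated muscle miRNAs, 2 had lower values in Trained (median log2 fold change -0.85, camera adjusted p = 0.0991), and miR-499-5p did not (0.04). This list passed with no filter (adjusted p = 0.00575), with the 10 CPM filter (0.0066), without Exposed 4 (0.0334) and without Trained 1 (0.0316), and its median was -0.53 without Exposed 2 (0.0601). These 4 calls were lost at adjusted p = 0.223 or more with an estimated correlation. That correlation was 0.10, 0.06, -0.26 and -0.17 in the 4 fits, so their loss does not show that the members moved together. Adjusted over the list alone, 2 of the 3 passed FDR 0.05 (miR-206-3p and miR-1a-3p), against 0 over all miRNAs. All 5 smooth muscle and stroma miRNAs had lower values in Trained (median -0.31, adjusted p = 0.1004), led by miR-143-3p at 7576 ± 481 CPM against 10642 ± 3303 CPM in Exposed (log2 fold change -0.49, and -0.25 without Exposed 2). These 5, which include both miR-199a-3p and miR-199b-3p, moved together (estimated correlation 0.46), so they are not separate results. This list passed with no filter (adjusted p = 0.0269) and without Exposed 4 (0.0166), calls lost at adjusted p = 0.432 and adjusted p = 0.474 with an estimated correlation. Without Exposed 2 its median was -0.05, with 3 of 5 lower (0.528), and 3 of 5 were lower also without Trained 1 (-0.35). All 6 red blood cell miRNAs had higher values in Trained (median 0.98, adjusted p = 0.183), but the median was -0.05 without Trained 3 and 0.61 without Exposed 2. These 6 moved together (estimated correlation 0.99), so they are not separate results. The list passed without Trained 2 (1.39, adjusted p = 0.00268), a call lost at adjusted p = 0.504 with an estimated correlation. Of the leukocyte miRNAs 3 of 4 were higher (median 0.55, adjusted p = 0.153), with miR-142-5p at 0.73 (0.13 without Trained 3) and miR-146a-5p at -0.10 (0.21 without Exposed 4). The median of these 4 was 0.13 without Trained 3. The list passed without Trained 2 (median 0.78 over the same 4 members and 0.60 over the 5 that passed the filter there, adjusted p = 0.00818), a call lost at adjusted p = 0.391 with an estimated correlation. The 4 epithelial miRNAs of the miR-200 set were all lower (median -0.20, adjusted p = 0.183), among them miR-200c-3p (-0.19) and miR-200b-3p (-0.21). Without Exposed 2 the miR-200 median was 0.06 with 3 of 4 higher, miR-200c-3p at 0.08 and miR-200b-3p at -0.05. Of the 7 neural miRNAs 4 were higher (median 0.00, adjusted p = 0.771), with miR-128-3p at -0.03 and miR-9-5p at 0.00, and the median lay below 0 without Exposed 2 (-0.0022), Exposed 4 (-0.04) or Trained 2 (-0.03) and reached 0.07 without Exposed 1. Liver and endothelial miRNAs had 2 and 1 tested members and were not tested as lists; the liver miRNA miR-192-5p stood at -0.02 and miR-194-5p at 0.19 (0.08 without Exposed 3).

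**Figure D3:**
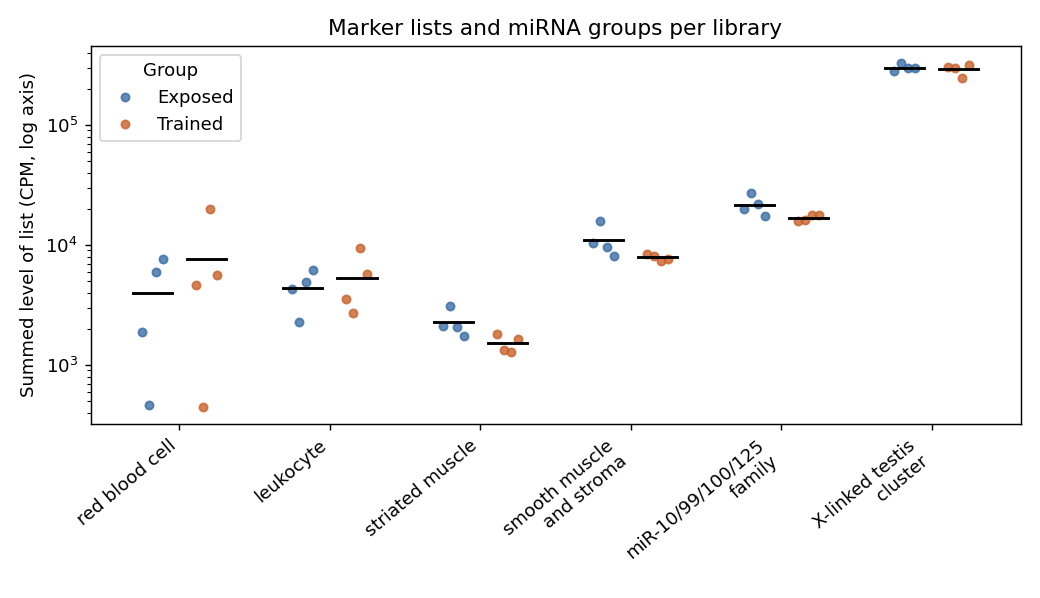
Summed level (CPM, log axis) of 6 miRNA lists in each library, with group means as black lines. The red blood cell list ranged from 450 CPM in Trained 2 to 19757 CPM in Trained 3, while the X-linked testis cluster ranged from 244002 to 327404 CPM.

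The remaining families and clusters gave no call with the preset correlation in the main fit. Of the 63 tested miRNAs named in the text, 54 moved by over 1.5 times and 25 turned sign when 1 library was left out. The miR-15/16 family was higher in 6 of 6 tested members (median 0.15, adjusted p = 0.0991), with a median of 0.0999 without Exposed 3. Its members miR-16-5p and miR-15a-5p stood at 0.14 and 0.17. The cluster inside an intron of Sfmbt2 was higher in 13 of 16 (0.09, adjusted p = 0.1004), although its most abundant member miR-669c-5p was at -0.23 and miR-467e-5p at 0.09. The summed level of this cluster went the other way. It was 20430 ± 2373 CPM in Trained and 23368 ± 1464 CPM in Exposed (SD, n = 4, exact permutation p = 0.0857, adjusted 0.357 over 25 lists). The imprinted Dlk1-Dio3 cluster was lower in 2 of 3 (-0.22, adjusted p = 0.114, and -0.12 without Trained 3), with miR-541-5p at -0.22 and miR-409-3p at 0.01. Higher values were found in 4 of 4 miR-181 members (0.33, adjusted p = 0.166), among them miR-181a-5p (0.55) and miR-181d-5p (0.12). Without Trained 3 the miR-181 median was 0.17 and miR-181a-5p stood at 0.14. The cluster of miR-290 to miR-295 was higher in 3 of 3 (0.12, adjusted p = 0.153), with miR-293-5p at 0.09 and miR-292-5p at 0.12, but in 1 of 3 without Exposed 2 (median -0.0027). Its median was 0.04 without Exposed 4, 0.35 without Exposed 1 and between 0.20 and 0.23 without Exposed 3, Trained 3 or Trained 4. Values were higher in 8 of 9 of the miR-17-92 clusters (median 0.06, adjusted p = 0.183), with miR-25-3p at 0.00 and miR-92a-3p at 0.01. The miR-17-92 median was 0.01 without Exposed 3 and 0.10 without Exposed 4. The let-7 family was split 6 higher and 7 lower (-0.05, adjusted p = 0.180), with let-7g-5p at 0.09, and its median lay above 0 (0.03 or less) without Exposed 1, Exposed 3, Trained 1 or Trained 4. It passed as lower without Exposed 2 (-0.16, adjusted p = 0.0483) and without Trained 3 (-0.14, 0.00276), calls lost at adjusted p = 0.594 and adjusted p = 0.387 with an estimated correlation. The miR-30 family was split 5 and 5 (0.03, adjusted p = 0.250), with miR-30d-5p and miR-30a-5p both at -0.03. The even split of miR-30 was lost without Trained 3 (9 of 10 higher, median 0.07), Exposed 4 (8 of 10, 0.05), Trained 2 (8 of 10, 0.07) or Exposed 2 (7 of 10, 0.07), and the median was 0.06 without Trained 1. The family of miR-34 and miR-449 was split 3 and 2 (0.01, adjusted p = 0.727), with miR-34b-3p at -0.04, and its median moved by over 1.5 times without any 1 library, from -0.01 without Trained 2 to 0.13 without Exposed 1. In 3 lists the median, the mean and the direction of camera differed in sign. These were the X-linked testis cluster (10 of 27 higher, median -0.02, adjusted p = 0.918), the family of miR-148 and miR-152 (2 of 5 higher, median 0.00, adjusted p = 0.771), with miR-148b-3p at 0.06, and the cluster of miR-183, miR-96 and miR-182 (1 of 3 higher, median -0.07, adjusted p = 0.866), with miR-183-5p at -0.07 and miR-182-5p at -0.14 (-0.01 without Trained 3). The X-linked median was 0.04 without Exposed 2 (18 of 27 higher), 0.06 without Trained 3 (23 of 27), -0.01 without Exposed 1 and -0.03 without Trained 4. That of miR-148 and miR-152 lay above 0 (0.08 or less) without any 1 library but Exposed 2 (-0.07) or Trained 2 (-0.0056). The median of the cluster of miR-183, miR-96 and miR-182 was -0.01 without Exposed 3 or Trained 3, -0.02 without Exposed 1 and -0.03 without Trained 1. The miR-29 and miR-26 families had 2 tested members each, all higher with all libraries, among them miR-26a-5p (0.12) and miR-26b-5p (0.20). Trained 3 set these directions, since without it the medians were -0.09 for miR-29 and -0.03 for miR-26, with miR-26a-5p at -0.07 and miR-26b-5p at 0.01. No member of the cluster of miR-302 and miR-367 was listed. Of the late, high-numbered entries of the miRNA registry, 16 were listed and 2 tested, miR-7214-5p and miR-6911-3p (0.38). Adjusted over the list alone, miR-7214-5p had FDR = 0.0394 over 2 tested members by edgeR, against 0.998 over all miRNAs. The adjustment within a list does not correct for the number of lists.

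The list of sperm miRNAs named in other work on paternal stress had 11 tested members, 4 higher and 7 lower in Trained (median log2 fold change -0.03, camera adjusted p = 0.693), and the median was 0.04 without Trained 3, 0.00 without Exposed 4, -0.01 without Exposed 2 and -0.0025 without Trained 2. Of these, 0 passed FDR 0.05 over all miRNAs or adjusted over the list alone. The tested members were miR-672-5p (-0.23), miR-200b-3p, miR-375-3p (-0.17), miR-30c-2-3p (-0.16), miR-30a-5p, miR-30a-3p (-0.03), miR-34c-5p, miR-449a-5p (0.07), miR-30c-5p (0.09), miR-34c-3p (0.11) and miR-32-5p (0.15). All 11 values turned or moved by over 1.5 times when 1 library was left out. Without Trained 3 they were -0.01 for miR-375-3p, -0.12 for miR-672-5p, 0.04 for miR-30a-3p, 0.00 for miR-30a-5p, 0.08 for miR-34c-5p and 0.24 for miR-32-5p, and without Exposed 2 -0.05 for miR-200b-3p. miR-30c-2-3p stood at -0.08 without Exposed 3, miR-34c-3p at 0.04 without Exposed 4, miR-449a-5p at 0.03 without Trained 2 and miR-30c-5p at 0.14 without Trained 1. miR-30c-1-3p, miR-32-3p, miR-204-5p, miR-532-3p and miR-449a-3p were listed with too few counts to be tested.

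The authors' deposited table gave an FDR under 0.05 to 0 of 387 miRNAs, and 20 had an unadjusted p under 0.05, 12 lower and 8 higher in Trained. The smallest FDR in the authors' deposited table, from edgeR, was 0.0676 for the liver miRNA miR-122-5p, at a mean count of 3.25 in Exposed and 0.75 in Trained. The authors' deposited table gave its next smallest p-values to miR-143-5p, miR-196b-5p, miR-615-3p and miR-206-3p. Apart from miR-206-3p, these had mean counts of 4.25 or less per group and failed the count filter used here. Fold changes in the authors' deposited table correlated with those computed here across the 226 tested miRNAs (Pearson r = 0.996), although miRNAs are not independent replicates. The p-values were not matched. With no filter, edgeR's exact test gave 11 miRNAs an unadjusted p under 0.05, and its quasi-likelihood test gave 18. For miR-122-5p the unadjusted p was 0.000175 in the authors' deposited table and 0.0527 by the quasi-likelihood test with no filter. By the latter test it was 0.0137 for miR-143-5p, 0.0396 for miR-196b-5p and 0.0210 for miR-615-3p, with FDR = 0.998 for each.

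Library measures were compared to see whether depth or complexity differed between the groups. Trained libraries held 383.5 ± 1.29 detected miRNAs and Exposed libraries 374.8 ± 4.11 (SD, n = 4; exact two-sided permutation p = 0.0286, the smallest that 4 against 4 allows; 0.0857 after Benjamini-Hochberg adjustment over 3 measures). All 4 Trained libraries were above all 4 Exposed libraries. Thinned to the lowest table total, the means were 376.3 ± 2.99 in Trained and 370.6 ± 0.81 in Exposed. Total counts were 253178 ± 10368 in Trained and 224686 ± 28657 in Exposed (SD, n = 4; exact permutation p = 0.143, adjusted 0.214). The 10 most abundant miRNAs took 51.2% ± 2.12 of counts in Trained and 51.4% ± 0.23 in Exposed (SD, n = 4; exact permutation p = 1). Trained 3 set this direction at 48.0%; without it the difference was 0.78 percentage points higher in Trained (exact permutation p = 0.0571, the smallest that 4 against 3 allows).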

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

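All weighed tests in this part were chosen after the results they measure had been seen. In 190 groups of 4 libraries examined, 11 had 1 library far from the other 3, where chance gives about 1 in 20, or 9.5. The flags therefore number about as many as chance gives, but all except that of miR-292-5p fell in Exposed 2 or Trained 3. Of those in Trained 3, 4 were miRNAs with 2 reads or fewer there. The groups share libraries and some share miRNAs, so the expected number is only a guide. It does not show that Exposed 2 and Trained 3 are like the other libraries. In Exposed 2, the summed miR-30 family stood at 38427 CPM against 35877 to 36280 CPM in the other Exposed libraries, the miR-200 epithelial list at 4223 CPM against 2331 to 2466 CPM, its member miR-200c-3p at 1966 CPM against 1020.3 to 1121 CPM, miR-206-3p at 704 CPM against 294 to 348 CPM, and miR-142-5p at 529 CPM against 939 to 987 CPM. In Trained 3, miR-186-5p stood at 673 CPM against 393 to 429 CPM in the other Trained libraries, and in Trained 2, miR-292-5p at 135 CPM against 79.2 to 85.1 CPM. The other 4 were miRNAs of a few reads in Trained 3: miR-122-5p at 0 CPM, miR-143-5p and miR-196b-5p both at 7.60 CPM, and miR-615-3p at 3.80 CPM. Their Trained 3 counts, in that order, were 0, 2, 2 and 1 reads, against 1, 1, 1 and 2 in each other Trained library. Gaps of 1 read do not set Trained 3 apart.

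Red blood cell miRNAs differed 43.9-fold between libraries, from 450 CPM in Trained 2 to 19757 CPM in Trained 3. A difference in table totals is argued against, since libraries with totals within 5% of each other differed by a median of 3.34 times. Blood cells in the sperm preparations are a candidate explanation: the red blood cell and leukocyte scores rose together over the 8 libraries (Pearson r = 0.90, permutation p = 0.00149; Spearman rho = 0.93, permutation p = 0.00223; adjusted over 6 relations, 0.00893 and 0.0134), and r was 0.83 without Exposed 2 and Trained 2. miR-451a, a marker of red blood cells, ranged from 29.1 CPM in Exposed 2 to 3637 CPM in Trained 3. The treatments are argued against as the cause of this spread, since libraries of one treatment differed 16.5-fold in Exposed and 43.9-fold in Trained, while a difference between the group means stays open (exact permutation p = 0.629).

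The family of miR-10, miR-99, miR-100 and miR-125 was lower in Trained in 7 of 7 tested members. Of 35 splits of the 8 libraries into 4 and 4, 1 gave a median as far from 0, the real one (0.38 in size, highest other 0.35), but this family was singled out among 20 lists because it passed, so chance is not excluded over the lists as a whole. Blood RNA as the whole cause was not decided. With miR-451a as a covariate the median moved little, to -0.33 (member SD 0.06, camera adjusted p = 0.00173), but the call was lost with an estimated correlation (adjusted p = 0.401). The members moved together (estimated correlation 0.61), so their SD does not measure the spread between libraries. RNA of striated muscle, or of smooth muscle and stroma, may account for some or all of it and cannot be told apart from a treatment difference. In deviations from group means, pooled over the 8 libraries, the family rose with the striated muscle score (Pearson r = 0.72, permutation p = 0.0260, adjusted over 6 relations 0.0632, Spearman rho = 0.57, permutation p = 0.151, adjusted 0.302, r = 0.40 without Exposed 2 and Trained 1). It also rose with the smooth muscle and stroma score (r = 0.80, permutation p = 0.0316, adjusted 0.0632, rho = 0.45, permutation p = 0.267, adjusted 0.401). That relation rests on Exposed 2 and Exposed 4 (r = -0.07 without them). Among Trained libraries it ran the other way, with the highest family and lowest stroma deviation in Trained 4 (0.079 and -0.15). The permutations mixed both groups, though the family deviated by up to 0.50 in Exposed and 0.079 in Trained, so they do not test a relation within 1 group. The median moved from -0.38 (member SD 0.06) to -0.15 (0.06) with the smooth muscle and stroma score as a covariate and to 0.047 (0.24) with the striated muscle score, which lay apart between the groups and so is confounded with them, and both fits ended the call (adjusted p = 0.0631 and 0.887) for a reason that was not tested.

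The authors' smallest p-values lay in miRNAs of few reads. Low counts are a candidate explanation: 80.0% of the 20 miRNAs with an unadjusted p under 0.05 in the authors' deposited table failed the count filter, against 41.6% of all 387 (Fisher's exact p = 0.000638). A difference between the treatments cannot be told apart from noise at these counts, and the smallest FDR of the authors' first 4 miRNAs was 0.998 by edgeR's quasi-likelihood test with no filter.

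The observed count of miRNAs past FDR 0.05 was 0, which all 35 of 35 splits must reach (highest other 35), so the splits say nothing about it. An unadjusted p under 0.05 in 10 miRNAs or more was given by 11 of 35 splits (highest other 69), and 1 list or more by 22 of 35 (highest other 6), so chance was not excluded for these last 2 counts. The split with 69 set Exposed 1, Exposed 3, Trained 2 and Trained 3 against the rest, so the libraries hold a structure that does not follow the groups.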

How the results depend on the processing

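Alternatives with other edgeR tests, covariates, reduced totals, thinning or 2 libraries left out together were chosen after seeing the data. Every alternative run gave 0 miRNAs past FDR 0.05. The count at an unadjusted p under 0.05 was 10, and it was 18 with no filter (387 miRNAs tested), 5 with the likelihood ratio test and 5 with the exact test of edgeR, 3 with the stroma covariate, and 5 to 13 when 1 library was left out. Its direction turned to mostly higher in Trained without Trained 2 (7 higher, 3 lower), without Exposed 2 and Trained 3 (7 and 2) and with the stroma covariate (2 and 1). The filter of 10 CPM in 4 libraries, meant to be stricter, kept 328 miRNAs because 10 CPM is 2 to 3 reads here. The number of lists past the threshold was 1, and it was 4 with no filter, 3 with the miR-451a covariate, 0 with the stroma covariate, 2 with the striated muscle covariate, 2 without Exposed 2 and Trained 3, 0 with an estimated correlation, 0 with fry, and 1 to 4 when 1 library was left out. With the replicate block, 4 lists and 0 miRNAs passed. The lists were the family of miR-10, miR-99, miR-100 and miR-125, red blood cell (adjusted p = 0.000113), striated muscle (0.0343) and smooth muscle and stroma (0.0333), all 4 lost at adjusted p = 0.536 with an estimated correlation. With no filter the other 3 past the threshold were striated muscle, smooth muscle and stroma, and the Sfmbt2 cluster. The Sfmbt2 cluster also passed with the 10 CPM filter, without Exposed 1 and with the miR-451a covariate, the let-7 family with that covariate, the family of miR-15 and miR-16 without Exposed 4, and the cluster of miR-290 to miR-295 without Exposed 1. Without Exposed 2 and Trained 3, and with the striated muscle covariate, the 2 lists were the let-7 family, lower, and the X-linked testis cluster, higher in Trained. Of 50 list calls over all alternatives, 0 held when the correlation was estimated (lowest adjusted p = 0.223 with an estimated correlation). By fry 2 passed, the Sfmbt2 cluster with the 10 CPM filter (0.0472) and the X-linked testis cluster without Exposed 2 and Trained 3 (0.0369). The 50 include repeats of 1 list test. For some of them the estimated correlation was near or below 0, as for the Sfmbt2 cluster with no filter (-0.00055). It was -0.058 for the family of miR-15 and miR-16 without Exposed 4. A lost call therefore does not by itself show that members moved together. DESeq2, limma-voom, the test without robust estimation and the other edgeR tests changed the tests of single miRNAs but not the values given to camera. Same-numbered libraries deviated together for replicates 2, 3 and 4 (r of 0.66, 0.69 and 0.49) but not for replicate 1 (r = -0.41). Between libraries of different number, r ranged from -0.78 (Exposed 2 with Trained 3) to 0.60 (Exposed 4 with Trained 3). The labels give no pairing, so the main fit used none, and a pairing by number is left open. The median of the family of miR-10, miR-99, miR-100 and miR-125 ranged from -0.44 to -0.16 when 1 library was left out, lowest in size without Exposed 2. The medians of the smooth muscle and stroma list and of the striated muscle list were near 0 with their own score as covariate, by construction. The striated muscle score did not overlap between the groups, so that fit is confounded with them. Detected miRNAs differed by 13.5 when 10 reads were required (exact permutation p = 0.0571), by 8.75 with the replicate block (p = 0.125, the smallest an exact sign-flip test of 4 pairs allows) and by 7.5 to 10.5 when 1 library was left out (p = 0.0571 at the least, so no threshold could be passed). The difference in percent of counts was 0.17 for the single most abundant miRNA, and for the 10 most abundant it ranged from -0.70 to 0.78 when 1 library was left out. Of 1660 log2 fold changes of 72 named miRNAs under alternatives, 1485 kept their direction and 0 passed FDR 0.05. The other 175, of 42 miRNAs, turned, 32 of them with the striated muscle covariate, and the cause was not tested. With RLE factors the value was -0.000818 for miR-92a-3p, and the list median was -0.00178 for the family of miR-34 and miR-449. With library totals alone the values were 0.0218 for miR-34c-5p, 0.0216 for miR-465b-5p, 0.00137 for miR-21a-5p, 0.0158 for miR-465c-5p, 0.00610 for miR-128-3p, 0.0294 for miR-148a-3p, 0.00294 for miR-30d-5p, 0.00260 for miR-30a-5p, 0.0293 for miR-25-3p, 0.0130 for miR-192-5p and 0.00330 for miR-30a-3p. There the list medians were 0.0294 for the family of miR-148 and miR-152, 0.0128 for the X-linked testis cluster and 0.00330 for the paternal stress list. With upper quartile factors the values were -0.0479 for miR-92a-3p, -0.0395 for miR-409-3p, -0.00289 for miR-499-5p and -0.0296 for miR-9-5p. With no filter the values were 0.0165 for miR-34c-5p, 0.0135 for miR-465b-5p, 0.00859 for miR-465c-5p, 0.0155 for miR-148a-3p, 0.0205 for miR-25-3p and 0.00389 for miR-192-5p, and the list medians, over all listed members, were 0.0334 for the let-7 family, -0.00398 for the miR-30 family, 0.0161 for the family of miR-148 and miR-152 and 0.0103 for the X-linked testis cluster. With the 10 CPM filter the values were 0.00587 for miR-34c-5p, 0.00369 for miR-465b-5p, 0.00930 for miR-148a-3p and 0.0118 for miR-25-3p. With DESeq2 the value was 0.00297 for miR-25-3p. With limma-voom the values were 0.000416 for miR-148a-3p, -0.00131 for miR-92a-3p and -0.00457 for miR-9-5p. With the replicate block the values were 0.00172 for miR-148a-3p and -0.00429 for miR-9-5p, and the list medians were 0.00172 for the family of miR-148 and miR-152 and -0.00429 for neural miRNAs. With the 10 most abundant left out of totals the values were -0.00430 for miR-92a-3p and -0.00140 for miR-9-5p. With the exact test and no filter the values were 0.0165 for miR-34c-5p, 0.0134 for miR-465b-5p, 0.00857 for miR-465c-5p, 0.0155 for miR-148a-3p, 0.0205 for miR-25-3p and 0.00362 for miR-192-5p. With the miR-451a covariate the values were 0.0101 for miR-34c-5p, 0.00133 for miR-25-3p, -0.0122 for miR-92a-3p, -0.303 for miR-3107-5p and -0.287 for miR-486-5p, and the list medians were 0.0122 for the X-linked testis cluster and -0.185 for red blood cell miRNAs. With the stroma covariate the values were 0.00824 for miR-34b-3p, 0.0609 for miR-200c-3p, 0.145 for miR-199a-3p and -0.00596 for miR-9-5p, and the list medians were 0.00722 for the X-linked testis cluster, 0.109 for the miR-200 set and 0.00904 for smooth muscle and stroma miRNAs. With the striated muscle covariate the values were 0.0658 for miR-34c-5p, 0.424 for miR-881-3p, 0.121 for miR-21a-5p, -0.0381 for miR-186-5p, 0.0251 for miR-206-3p, 0.204 for miR-1a-3p, -0.266 for let-7g-5p, 0.0637 for miR-34b-3p, 0.0467 for miR-10b-5p, 0.0746 for miR-30d-5p, -0.373 for miR-26a-5p, -0.232 for miR-26b-5p, -0.234 for miR-148b-3p, -0.000704 for miR-15a-5p, -0.0406 for miR-181a-5p, -0.382 for miR-92a-3p, -0.274 for miR-293-5p, -0.211 for miR-292-5p, -0.128 for miR-467e-5p, 0.00336 for miR-541-5p, -0.306 for miR-409-3p, 0.04997 for miR-182-5p, 0.545 for miR-200c-3p, 0.147 for miR-200b-3p, -0.960 for miR-3107-5p, -0.894 for miR-486-5p, -0.436 for miR-142-5p, -0.274 for miR-499-5p, 0.0204 for miR-143-3p, 0.213 for miR-375-3p, -0.0400 for miR-449a-5p and 0.0527 for miR-30a-3p. There the list medians were 0.0467 for the family of miR-10, miR-99, miR-100 and miR-125, -0.0311 for the miR-17-92 clusters, -0.211 for the cluster of miR-290 to miR-295, 0.276 for the X-linked testis cluster, 0.04997 for the cluster of miR-183, miR-96 and miR-182, 0.257 for the miR-200 set, -0.912 for red blood cell miRNAs, -0.120 for leukocyte miRNAs, 0.0251 for striated muscle miRNAs, 0.0204 for smooth muscle and stroma miRNAs, -0.0938 for neural miRNAs and 0.0527 for the paternal stress list. Without Exposed 2 and Trained 3 the values were 0.102 for miR-34c-5p, 0.229 for miR-881-3p, 0.0648 for miR-21a-5p, 0.0287 for miR-465c-5p, -0.0424 for let-7g-5p, 0.0870 for miR-34b-3p, 0.0773 for miR-30d-5p, 0.0398 for miR-30a-5p, -0.0985 for miR-26a-5p, -0.0259 for miR-26b-5p, 0.0492 for miR-25-3p, -0.0901 for miR-92a-3p, -0.0878 for miR-293-5p, -0.0430 for miR-409-3p, 0.0388 for miR-182-5p, 0.257 for miR-200c-3p, 0.00238 for miR-200b-3p, -0.522 for miR-3107-5p, -0.497 for miR-486-5p, -0.0219 for miR-142-5p, -0.0414 for miR-499-5p, 0.0964 for miR-375-3p and 0.0725 for miR-30a-3p. There the list medians were 0.197 for the X-linked testis cluster, 0.0388 for the cluster of miR-183, miR-96 and miR-182, 0.0388 for the miR-200 set, -0.430 for red blood cell miRNAs and 0.0964 for the paternal stress list. When 1 library was left out, the list medians that turned ranged from -0.161 to 0.0298 for the let-7 family, from -0.0656 to 0.0779 for the family of miR-148 and miR-152, from -0.00265 to 0.349 for the cluster of miR-290 to miR-295, from -0.0326 to 0.0612 for the X-linked testis cluster, from -0.275 to 0.0562 for the miR-200 set, from -0.0430 to 0.0718 for neural miRNAs, from -0.0327 to 0.0370 for the paternal stress list, from -0.0130 to 0.127 for the family of miR-34 and miR-449 and from -0.0530 to 1.47 for red blood cell miRNAs. Over the same fits the fold changes ranged from -0.0603 to 0.0454 for miR-465b-5p, from -0.0417 to 0.0253 for miR-465c-5p, from -0.115 to 0.0819 for miR-128-3p, from -0.0656 to 0.0724 for miR-148a-3p, from -0.0119 to 0.0371 for miR-25-3p, from -0.0698 to 0.0491 for miR-192-5p, from -0.190 to 0.105 for miR-881-3p, from -0.108 to 0.0817 for miR-21a-5p, from -0.0950 to 0.0184 for miR-34b-3p, from -0.0559 to 0.0212 for miR-30d-5p, from -0.0561 to 0.104 for miR-92a-3p and from -0.0307 to 0.243 for miR-293-5p. They ranged also from -0.0636 to 0.349 for miR-292-5p, from -0.0358 to 0.0794 for miR-409-3p, from -0.287 to 0.0828 for miR-200c-3p, from -0.0504 to 0.149 for miR-499-5p, from -0.225 to 0.0859 for miR-199a-3p, from -0.0329 to 0.0776 for miR-34c-5p, from -0.348 to 0.206 for miR-146a-5p, from -0.0568 to 0.0370 for miR-30a-3p, from -0.0251 to 0.1003 for miR-9-5p, from -0.0327 to 0.00123 for miR-30a-5p, from -0.0663 to 0.224 for miR-26a-5p, from -0.152 to 1.39 for miR-3107-5p and from -0.129 to 1.38 for miR-486-5p. Depth limits the miRNAs left out by the filter, which had few reads. The median 95% interval of a fold change had a half-width of 0.45 on the log2 scale. Whether depth or the spread between samples set that width was not tested.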

Other observations

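Sperm libraries carried miRNAs from both arms of 43 hairpins at tested levels, with the 5p arm higher in 26 and the 3p arm higher in 17. The balance between the arms passed FDR 0.05 in 0 hairpins between Trained and Exposed (limma, smallest FDR 0.939), with 1 at an unadjusted p under 0.05, miR-342. The first principal component of the tested miRNAs held 67.4% of the variance, and miR-451a, miR-144-3p and miR-3107-5p, all of the red blood cell list, had the largest loadings. Spearman correlations between libraries across miRNAs ranged from 0.91 to 0.99, with a median of 0.97 both within Exposed and between the groups.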
